A study of Mus musculus with 24 samples.

How the data were processed

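RNA sequencing counts per gene were measured in mouse oocytes, 5 pooled per library, in 12 deposited columns that form 6 groups of 2. Per the labels' protocols, cDNA was made with a full-length single-cell amplification kit and libraries with a transposase kit. The counts used here are those deposited by the authors for 55401 genes. The submitters' processing notes list fastp 0.12.4, HISAT2, featureCounts, SAMtools, Picard, DESeq2, Bowtie2 2.2.5 and deepTools 3.5.1 with the mouse build mm10, and do not state the role, order or parameters of each, so which tool made the counts is not stated. The values were checked to be whole numbers of raw-count size. CUT&Tag libraries for H4K16 acetylation belong to the same series and were not analysed here.

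Depth per column ran from 6.22 M to 35.6 M counts, so that the floor of 3 counts corresponded to between 0.0842 and 0.482 CPM. The 2 in vivo PSMPs columns were tested against counting noise with a chi-square statistic over genes with at least 20 counts, found to differ by less than that noise (15.6% of genes had equal values), and merged as their rounded mean, which left 11 libraries. That group was counted as 1 sample and assumed to vary like the others. Groups were taken from the labels. The labels state neither the control of SAHA nor the route of exposure of the overexpressing oocytes, so each was compared with both candidates.

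Analysis was done in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by edgeR's expression filter (minimum count 10), which left 16736. Libraries were scaled by TMM (factors from 0.542 to 1.57), and a model with 1 coefficient per group was fitted to all libraries with robust quasi-likelihood dispersion, leaving 5 residual degrees of freedom. The biological coefficient of variation was 71.9%. Contrasts were tested with edgeR's quasi-likelihood F test, and p-values were adjusted by the Benjamini-Hochberg method over genes, with 0.05 as threshold. Standard errors were taken from the fold change and its F statistic. A gene at 0 in a whole group was given a bound on its fold change, computed against 3 counts over the group, and a gene with 1 to 3 counts a ratio with a 95% Poisson interval.

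For gene sets, 30 lists of 838 genes were written by hand before the data were examined, and 8 of those genes were not in the file. Lists with at least 5 measured members were tested with limma's camera at an inter-gene correlation of 0.01 and again with the correlation estimated from the data, each adjusted over lists. Counts of members adjusted over the list alone use the Benjamini-Hochberg method within the list. Gene sets from 1 comparison were tested in the same way in comparisons that share no library with it. Where identifiers shared a symbol (217 identifiers in all), the lists used the identifier with the most counts, and the gene tests kept each identifier apart.

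Genes named in the text were chosen by a rule written before the data were examined. For each comparison it took the 10 largest rises and the 10 largest falls among genes past the threshold with a mean of at least 10 CPM in the higher group and no overlap between the libraries of the groups, leaving out unnamed gene models. It took 5 per direction for the difference between the PSMPs effects, and the 5 of smallest p per direction where none passed. Some genes the rule took are not reported here. Histone deacetylase genes and Kat8 were always tabulated, and of them only Hdac1, Hdac3, Hdac4 and Hdac7 passed in any comparison with TMM factors, while Hdac2 passed in 3 with library totals. Examples within lists were chosen after their values were seen, as were H1f8 in in vitro PSMPs and Arf6, Dyrk1a and Cdkn1b between the controls.

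Alternatives set before the data were examined were a filter at 50 counts, no filter, mitochondrially encoded genes left out, DESeq2's size factors, DESeq2's Wald test, a fold change threshold of log2 1, the estimated correlation, a replicate block, a fit to only the groups of a comparison, sets of the 100 genes of smallest p, and leaving out each deposited column in turn. Added after the data were seen were the in vivo PSMPs columns as 2 libraries, library totals in place of TMM factors, and only genes with at least 10 counts in every library. No comparison had 3 libraries per group, so other splits of the samples were not counted.

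The procedure was tested on simulated data with 1 mean per gene in all libraries and the trend of spread fitted over all groups. The data were less even, with replicates correlated at 0.855 in con and 0.983 in PSMPs & OE-Hdac3 and fewer genes detected in the controls. Neither feature was simulated, so the error counts that follow need not hold for these data. With 1 library against 2, as for in vivo PSMPs, edgeR recovered 6 of 100 genes with a simulated 4-fold change and 38 of 100 with a 16-fold change and called 4 of 16505 unchanged genes, while DESeq2 recovered 7 and 49 and called 149. With 2 against 2, edgeR recovered 13 and 70 and called 2 unchanged genes, while DESeq2 recovered 21 and 85 and called 78. A list raised by log2 1 was recovered in both, and 0 of the other lists were called.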

Results

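Gene expression was measured in mouse oocytes by RNA sequencing in 6 groups of 2 libraries, each library made from 5 pooled oocytes. The groups were controls (con), oocytes exposed in the animal to polystyrene microplastics (in vivo PSMPs), controls for culture (con-in vitro) and oocytes exposed in culture (in vitro PSMPs). The other two were oocytes treated with SAHA, a pan-inhibitor of histone deacetylases also called vorinostat (SAHA), and exposed oocytes in which the histone deacetylase gene Hdac3 was overexpressed (PSMPs & OE-Hdac3). Total counts were 30.7 M and 35.6 M in con, 30.5 M and 30.5 M in in vivo PSMPs, and 6.22 M and 6.40 M in con-in vitro. They were 10.0 M and 12.6 M in in vitro PSMPs, 19.2 M and 19.4 M in SAHA, and 9.81 M and 7.03 M in PSMPs & OE-Hdac3. The 2 in vivo PSMPs columns differed by less than counting noise (chi-square over degrees of freedom 0.444, against 16.5 to 384 in the other groups). They were counted as 1 sample (n = 1), which was assumed to vary like the other groups. Nothing in the labels says that the libraries of a group came from separate animals, so p-values measure the spread between these libraries, and intervals and floors cover counting error only. Levels are TMM-normalised CPM, given as mean ± SD with n = 2 unless stated. Values of log2 fold change are given ± standard error, and adjusted p-values are Benjamini-Hochberg values from edgeR's quasi-likelihood F test over 16736 genes.

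The libraries differed in how many genes they held. With at least 1 count, 12316 and 12843 genes were detected in con and 11832 and 11640 in con-in vitro, against 17722 in in vivo PSMPs and 20284 to 20957 in the in vitro PSMPs, SAHA and PSMPs & OE-Hdac3 libraries. The 100 most abundant genes took 52.2% and 53.3% of the counts in con-in vitro, and 19.0% to 36.1% in the other libraries. Many genes were therefore at 0 in a control group, and their folds are given as lower bounds against a floor of 3 counts over the group.

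**Figure D1:**
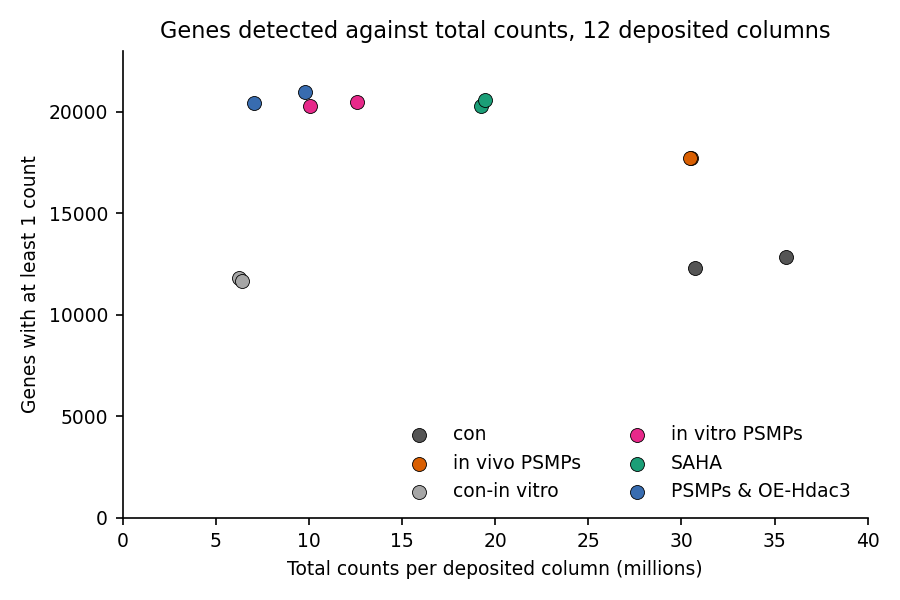
Genes with at least 1 count (vertical axis) against total counts (horizontal axis), 1 point for each of the 12 deposited columns, coloured by group. The con and con-in vitro columns lie between 11640 and 12843 genes at totals from 6.22 M to 35.6 M, below the in vivo PSMPs columns and all others.

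The level of Hdac3 was examined first, since 1 group was labelled as overexpressing it. Hdac3 (ENSMUSG00000024454.16, mm10 chromosome 18, 37935844 to 37955016) encodes a class I histone deacetylase that works in the NCoR and SMRT corepressor complexes. It stood at 336 and 228 CPM in the PSMPs & OE-Hdac3 libraries. It stood at 23.4 and 37.4 CPM in con, 12.7 CPM in in vivo PSMPs, 26.7 and 23.8 CPM in con-in vitro, 15.3 and 9.37 CPM in in vitro PSMPs, and 7.47 and 7.17 CPM in SAHA. The mean of the PSMPs & OE-Hdac3 libraries was 15.5 times the mean of the others. Among the exposed and treated groups without overexpression, Hdac3 was lower in SAHA than in con (log2 -2.05 ± 0.45, adjusted p = 0.015) and than in con-in vitro (log2 -1.79 ± 0.45, adjusted p = 0.026). The PSMPs groups did not pass the test, with log2 -1.26 ± 0.56 (adjusted p = 0.19) for in vivo PSMPs against con and log2 -1.03 ± 0.44 (adjusted p = 0.14) for in vitro PSMPs against con-in vitro, the latter -0.00098 when scaled by library totals. Both SAHA calls were lost without either SAHA library, with adjusted p from 0.076 to 0.139 and log2 from -1.76 to -2.08. The one against con-in vitro was lost as well without con-in vitro replicate 1 (adjusted p = 0.0502) and with library totals in place of TMM factors (log2 -1.07, adjusted p = 0.121). With only the groups of the comparison fitted, both calls were lost (log2 -2.11, adjusted p = 0.086 against con, and log2 -1.64, adjusted p = 0.083 against con-in vitro).

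**Figure D2:**
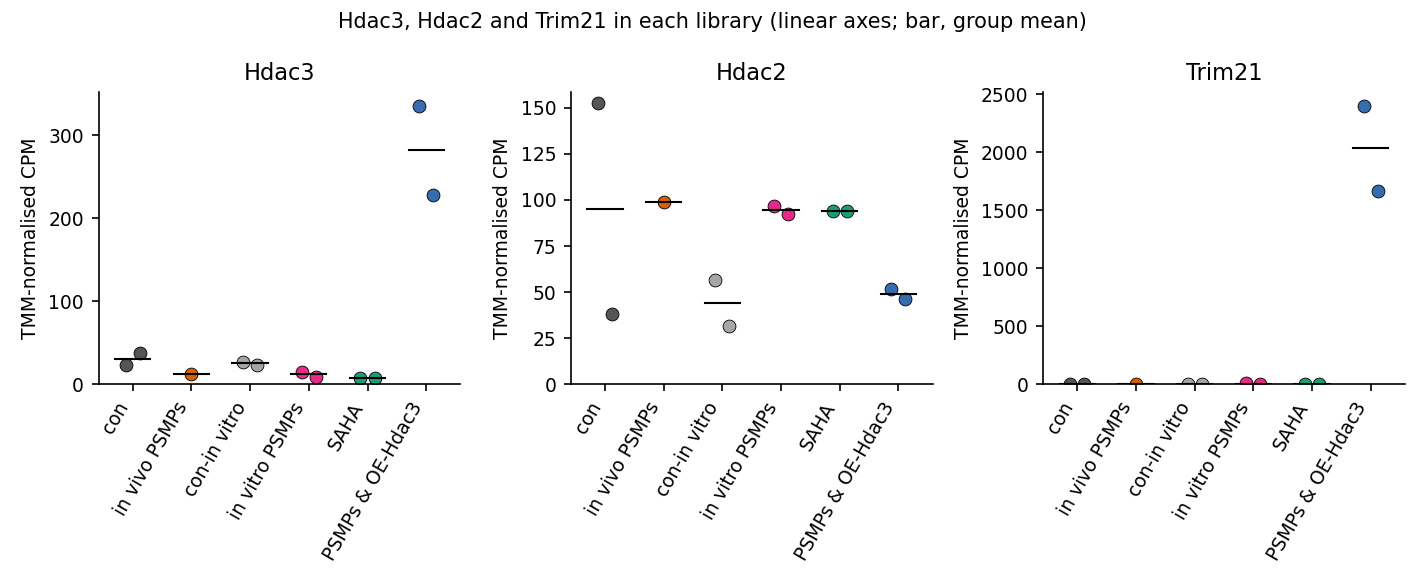
TMM-normalised CPM of Hdac3, Hdac2 and Trim21 on linear axes, 1 point per library in the 6 groups and a bar at each group mean (in vivo PSMPs, n = 1). Hdac3 reaches 228 and 336 CPM and Trim21 1668 and 2398 CPM in the PSMPs & OE-Hdac3 libraries, above every other library.

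Exposure in the animal was followed mainly by genes that the con libraries did not hold. Inha, the alpha subunit of inhibin, a hormone of granulosa cells, stood at 59.4 CPM in the in vivo PSMPs library and at 0 counts in con, at least 1339-fold higher (ENSMUSG00000032968.4, chromosome 1, 75507077 to 75510366). The translation initiation factor gene Eif1a was at least 1204-fold higher, the NEDD8-conjugating enzyme gene Ube2f at least 1176-fold and the adaptor complex gene Ap4e1 at least 1123-fold. Further genes at 0 in con were Ndst1 for heparan sulfate synthesis (at least 887-fold higher), the ribosomal protein kinase gene Rps6kb2 (at least 596-fold) and Rhou (at least 578.5-fold). The same held for the homologous recombination gene Xrcc3 (at least 539-fold), Rnf217 (at least 526-fold) and Ccdc170 (at least 503-fold). Fewer genes fell. Zfp595 and Xk were at 0 in the exposed library, at least 182-fold and 141-fold lower, and Btbd3 held 1 count there, a ratio of 620 with a 95% counting interval of 111 to 24480 lower. The DNA polymerase epsilon subunit gene Pole2 fell from 23.2 ± 7.62 to 0.902 CPM (log2 -4.67 ± 0.96). The pyrophosphate transporter gene Ank fell from 92.3 ± 16.5 to 7.42 CPM (log2 -3.63 ± 0.83), and Prkar2a, a regulatory subunit of protein kinase A, fell from 105.5 ± 30.7 to 11.2 CPM (log2 -3.23 ± 0.64). Gatb (log2 -5.82 ± 1.36), Tceanc (log2 -5.01 ± 0.80), the RNA-binding protein gene Rbm47 (log2 -3.18 ± 0.51) and Krcc1 (log2 -3.08 ± 0.61) fell as well. The adjusted p of these 20 genes lay between 0.023 and 0.047.

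By list, cytosolic ribosomal protein genes were shifted upward in the in vivo PSMPs library, with 71 of 75 measured members above con and a median log2 of 1.60 against 0.25 over all genes. The median log2(CPM + 1) over members was 3.20 in con replicate 1, 5.49 in con replicate 2 and 6.44 in in vivo PSMPs. On this measure the con libraries differed more from each other than con replicate 2 did from in vivo PSMPs. Of the 75, 1 rose (Rps26, 42.4 against 4.36 ± 3.17 CPM, log2 3.28 ± 0.72, adjusted p = 0.046) and 74 did not pass the test, 0 adjusted over the list alone, with Rps16 at 188 against 61.9 ± 4.33 CPM (adjusted p = 0.093). The list test gave adjusted p = 0.00064, and adjusted p = 0.817 with an estimated correlation, a value that every list of this comparison named here shared. The 20 cumulus and granulosa cell markers had a median log2 of 6.56 (3.86 with genes at 0 in con set to their bounds), and 14 of them were at 0 in con. Inha and Vcan (3.25 CPM, at least 73.2-fold higher) rose, and 12 rose adjusted over the list alone (list test adjusted p = 0.031). Gja1 at 13.4 CPM and Cyp11a1 at 20.0 CPM against 7.64 and 4.59 CPM in con did not pass the test over all genes. All 13 mitochondrially encoded genes had fitted values below con (median log2 -1.12, list test adjusted p = 0.031), and none passed alone, with mt-Co1 at log2 -1.62 ± 0.80 (adjusted p = 0.24). Maternal mRNA clearance genes had a median log2 of -0.57 (20 measured, none called, adjusted p = 0.034), with Pan2 at log2 -1.48 ± 0.50 (adjusted p = 0.092). The DNA and histone methylation list had a median of -0.39 (26 measured, adjusted p = 0.034), with the H3K4 methyltransferase gene Kmt2b lower (log2 -1.85 ± 0.45, adjusted p = 0.0498) and 1 member higher and 1 lower adjusted over the list alone. Of the 39 meiotic cell cycle genes, Fbxo5, whose protein inhibits the anaphase-promoting complex, rose from 16.2 ± 6.89 to 88.2 CPM (log2 2.44 ± 0.47, adjusted p = 0.046), and the other 38 did not pass. Single members of other lists passed as well. Trp53, a tumour suppressor and regulator of the damage response, fell from 75.9 ± 3.58 to 11.03 CPM (log2 -2.78 ± 0.61) and the chaperone gene Hspa5 rose from 34.0 ± 1.70 to 116 CPM (log2 1.78 ± 0.40). The nucleotide and serine synthesis genes Cad, Gart, Psat1 and Ppat stood at 5.93, 4.23, 4.15 and 2.04 CPM and at 0 in con, at least 134-fold, 95.3-fold, 93.5-fold and 45.9-fold higher.

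In all, 769 genes were higher and 48 lower in in vivo PSMPs than in con, and 609 of the 769 (79.2%) were at 0 in both con libraries. The median level of the higher genes was 3.15 CPM. The count rested on the control libraries, since it was 2807 without con replicate 1, where no list was called, and 4336 without con replicate 2. The count was 0 when only these groups were fitted (433 at an unadjusted p under 0.05), where the spread, the filter and the scaling all changed. DESeq2 gave 2693 in the 6-group fit. Among genes with 10 counts in every library, which leaves out those at 0 in con, the count was 22.

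In vitro PSMPs differed from con-in vitro by far lower levels of a set of transcripts abundant in con-in vitro. For several genes con-in vitro was the group that stood apart, since con held Arf6 at 28.0 and 63.3 CPM, Cdkn1b at 8.03 and 2.37 CPM and H1f8 at 13468 and 11938 CPM, closer to the in vitro PSMPs levels below than to con-in vitro. Lsm14b, at 1892 and 1714 CPM in con, lay below both controls in in vitro PSMPs. In a count chosen after the data were seen, 961 of the 1435 genes called higher were also called lower in con-in vitro than in con (15 higher), and 703 of the 1135 lower were called higher there (37 lower). The contrasts share the con-in vitro libraries, so part of this is expected without an effect of exposure or culture. Lsm14b, an RNA-binding protein of oocyte messenger ribonucleoprotein particles, fell 345-fold (log2 -8.43 ± 0.62, adjusted p = 0.0001). Arf6, a small GTPase of membrane traffic, fell from 8241 ± 715 to 12.8 ± 0.661 CPM (log2 -9.33 ± 0.55). Cdkn1b, the inhibitor of cyclin-dependent kinases, fell from 2353 ± 116 to 3.96 ± 1.71 CPM (log2 -9.21 ± 0.83). The linker histone gene H1f8, specific to oocytes and chosen after its values were seen, rose from 807 ± 8.83 to 11816 ± 1419 CPM (log2 3.87 ± 0.28, adjusted p = 9.7e-05). Also lower were Pced1b (log2 -9.31 ± 0.58), Tspyl1 (log2 -9.03 ± 0.56), the kinase gene Dyrk1a (log2 -8.97 ± 0.62), and the ubiquitin ligase genes Trim65 (log2 -8.83 ± 1.69) and Fbxo46 (fell 363-fold). Cercam and Shisa4 were at 0 in in vitro PSMPs, at least 175-fold and 143-fold lower. Genes at 0 in con-in vitro included Tada1 of the SAGA acetyltransferase complex (71.1 ± 18.7 CPM, at least 167-fold higher), the centromere gene Cenpu (58.5 ± 10.1 CPM, at least 137-fold) and Fmr1nb (at least 120.4-fold). Others were Wdr61 of the PAF and SKI complexes (at least 107-fold), the autophagy protease gene Atg4a (at least 92.3-fold) and the guanylate kinase gene Guk1 (at least 56.0-fold). Efcab12 (at least 62.6-fold), Serpinb3a (at least 58.7-fold), Tmem74 (at least 56.3-fold) and Hsd17b13 (at least 52.7-fold) completed the 20 taken by the naming rule.

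Genes for maternal mRNA clearance were shifted downward as a list, and of 20 measured 0 rose, 8 fell and 12 did not pass (9 fell adjusted over the list alone). They had a median log2 of -1.06 against 0.71 over all genes (list test adjusted p = 0.00024, and adjusted p = 0.656 with an estimated correlation, a value shared by the 5 lists called here). Their summed level, which weighs abundant members most, stood apart in con-in vitro (86272 and 91085 CPM). By this sum in vitro PSMPs (10148 and 13829 CPM) lay near con (14730 and 10863 CPM). The median log2(CPM + 1) over members differed from this, with con-in vitro (7.27 and 7.91) near con (7.35 and 7.61). In vitro PSMPs (6.22 and 7.08) lay below both controls on that measure. Besides Lsm14b the lower genes included the deadenylase subunit gene Pan3 (log2 -6.17 ± 0.51) and the m6A reader gene Ythdf2 (1356 ± 178 to 139 ± 0.459 CPM). Btg4, the adaptor that recruits the CCR4-NOT deadenylase during meiotic maturation, was lower too (log2 -2.39 ± 0.39, adjusted p = 0.004). In the DNA and histone methylation list 2 of 26 rose, 8 fell and 16 did not pass (2 and 12 adjusted over the list alone), with a median of -1.06 (adjusted p = 0.00024). Uhrf1 (log2 -4.59 ± 0.34), the de novo DNA methyltransferase gene Dnmt3a (1365 ± 24.0 to 73.7 ± 21.3 CPM) and Kmt2d (log2 -2.51 ± 0.34) fell, and the imprint-protecting zinc finger gene Zfp57 rose (log2 4.54 ± 0.60). Nuclear genes of oxidative phosphorylation were shifted upward, 23 of 76 higher and 0 lower, with 53 not called and 23 higher adjusted over the list alone (median 1.38, adjusted p = 0.0011). Their sums were 1735 and 1520 CPM in con-in vitro, 3009 and 4542 CPM in con and 4746 and 4754 CPM in in vitro PSMPs. Cox8a went from 8.35 ± 1.32 to 178 ± 63.1 CPM (log2 4.41 ± 0.40), Cox6c rose by log2 3.64 ± 0.45, Ndufa1 by 4.07 ± 0.53 and Cox7a2 by 3.31 ± 0.43. In the oocyte identity list 10 of 35 rose and 2 fell, 13 and 2 adjusted over the list alone (median 1.51, adjusted p = 0.046). By the summed level con-in vitro stood apart here too (22540 and 25031 CPM). The sums were 65003 and 65037 CPM in con and 66533 and 84652 CPM in in vitro PSMPs. The median log2(CPM + 1) over members differed from this, with con-in vitro (8.17 and 8.83) between con replicate 1 and con replicate 2 (9.16). On that measure in vitro PSMPs (9.92 and 9.98) lay above both controls. Among the higher were the antiapoptotic gene Bcl2l10 (log2 2.53 ± 0.32), Mos, the kinase that holds the metaphase arrest (log2 2.64 ± 0.35), and Dppa3 (log2 3.42 ± 0.45). Subunits of the HDAC corepressor complexes had a median of -0.69 (2 of 23 higher, 4 lower, 2 and 5 adjusted over the list alone, adjusted p = 0.046), a median that turned to 0.26 when scaled by library totals. Gatad2b (log2 -5.73 ± 0.51), Sin3b (log2 -3.15 ± 0.35) and Chd4 (log2 -2.50 ± 0.52) fell, and Rbbp7 rose (log2 2.75 ± 0.36).

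Other lists did not pass as a whole but held single genes that did. Of 39 meiotic cell cycle genes 11 rose and 3 fell, 14 and 3 adjusted over the list alone (median 0.84, adjusted p = 0.168). They included Pttg1, which encodes securin (log2 4.48 ± 0.50), Aurkc, the germ-cell Aurora kinase (18.8 ± 3.13 to 155 ± 13.9 CPM), and the cyclin genes Ccnb1 (log2 3.12 ± 0.37) and Ccnb2 (log2 2.56 ± 0.33). Of 13 genes of the MOF complexes, which acetylate H4K16, Msl3 (log2 2.27 ± 0.36) and Mcrs1 (log2 1.71 ± 0.39) rose, and 3 fell, among them Msl1 (log2 -2.05 ± 0.50) and Msl2 (log2 -3.78 ± 0.93) (list test adjusted p = 0.636). Of 31 proteasome subunits 8 rose and 0 fell (median 0.98, adjusted p = 0.063), led by Psmd2 (10.9 ± 1.44 to 124 ± 22.2 CPM) and Psma2 (log2 3.39 ± 0.59).

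The test called 1435 genes higher and 1135 lower in in vitro PSMPs than in con-in vitro, 426 of the higher ones at 0 in con-in vitro. Efcab12, Cercam, Shisa4 and Trim65 lost their calls without either in vitro PSMPs library. The count fell to 1126 without in vitro PSMPs replicate 1, where 3 lists passed, and to 1096 without replicate 2, and DESeq2 gave 4602. Scaling by library totals moved the median of all genes from 0.71 to 1.70 and the split to 3473 higher and 758 lower, so directions here are relative to the bulk of genes.

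SAHA was compared with each control, as the labels do not say which one belongs to it. Against con-in vitro the genes that moved most were largely those above. Tada1 (114 ± 17.9 CPM, at least 267-fold higher), Wdr61 (113 ± 16.1 CPM, at least 264-fold), Cenpu (at least 186-fold), Fmr1nb (at least 165-fold), Atg4a (at least 155-fold) and Tmem74 (at least 97.8-fold) were at 0 in con-in vitro. So were the transcriptional inhibitor gene Id2 (98.1 ± 26.8 CPM, at least 229.9-fold), Lsm4 (at least 152-fold), Tktl1 (at least 104-fold) and Snapin (at least 91.1-fold). Arf6 (log2 -10.14 ± 0.57), Dyrk1a (log2 -10.12 ± 0.65), Tspyl1 (log2 -9.93 ± 0.58) and Otub1, a deubiquitinase gene (log2 -9.65 ± 1.46) fell, as did Trim65 (log2 -9.63 ± 1.74), Cdkn1b (log2 -9.44 ± 0.84), the phosphoinositide phosphatase gene Mtmr2 (log2 -9.16 ± 0.51) and Fbxo46 (log2 -8.87 ± 0.84). Cercam and Shisa4 were at 0, at least 249-fold and 204-fold lower. Both contrasts use the same con-in vitro libraries, so this likeness is not independent. Of the genes called in SAHA, 1100 of 1950 higher were also called lower in con-in vitro than in con (30 higher), and 749 of 1363 lower were called higher there (43 lower). These contrasts share the con-in vitro libraries with opposite sign, so part of this is expected without an effect of SAHA. Hdac1 was at 11.5 ± 1.85 CPM against 0 (at least 26.9-fold higher, adjusted p = 0.046), a call lost without any 1 of the 4 libraries.

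Among the lists, 1 maternal mRNA clearance gene of 20 rose and 7 fell in SAHA against con-in vitro, 1 and 8 adjusted over the list alone (median -1.14 against 0.66 over all genes, adjusted p = 0.0038, and adjusted p = 0.754 with an estimated correlation, a value shared by the 4 lists called here). Against con this list did not pass (median -0.06, 3 higher, 4 lower, adjusted p = 0.379). Its sums in SAHA (15700 and 14400 CPM) lay near con, with con-in vitro apart. By the median log2(CPM + 1) over members SAHA (6.91 and 7.06) lay below con (7.35 and 7.61) and con-in vitro (7.27 and 7.91). Lsm14b (log2 -8.73 ± 0.63), Pan3 (log2 -5.74 ± 0.50) and Btg4 (log2 -1.97 ± 0.38) fell. In the methylation list 2 of 26 rose and 9 fell, 2 and 9 adjusted over the list alone (median -0.91, adjusted p = 0.0038), among the lower Uhrf1 (log2 -4.55 ± 0.34), Dnmt3a (log2 -4.10 ± 0.39) and Setdb1 (log2 -2.71 ± 0.37). Ribosomal protein genes had a median of -1.36 (3 of 75 higher, 6 lower, 2 and 2 adjusted over the list alone, adjusted p = 0.0040), with Rps12 (log2 -2.85 ± 0.50) lower and Rpl41 (log2 2.25 ± 0.39) higher. Oxidative phosphorylation genes had a median of 1.37 (23 of 76 higher, 1 lower, 25 and 1 adjusted over the list alone, adjusted p = 0.0094), with Cox8a (log2 4.44 ± 0.40) and Cox6c (16.5 ± 4.78 to 285 ± 44.5 CPM) higher. Against con the oxidative phosphorylation list did not pass (median 0.04, 14 higher, 5 lower, adjusted p = 0.998). Meiotic cell cycle genes did not pass as a list (adjusted p = 0.067), while 13 of 39 rose and 2 fell, Ccnb1 (495 ± 134 to 7606 ± 247 CPM) and Aurkc (log2 3.32 ± 0.35) among the higher. The test called 1950 genes higher and 1363 lower, a split of 3222 and 922 with library totals, which moved the median of all genes from 0.66 to 1.37. The count was 1148 without SAHA replicate 1, where 7 lists passed, and 1111 without SAHA replicate 2, and DESeq2 called 5327. Lsm4, Tktl1, Snapin, Cercam, Shisa4, Trim65 and Hdac1 lost their calls without either SAHA library.

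Against con, SAHA libraries held many genes that con lacked. Id2 (at least 2210.5-fold higher), Rrp1b (87.4 ± 9.91 CPM, at least 1970.2-fold), Zmym1 (at least 1105-fold) and the chromatin remodeller gene Hltf (at least 918-fold) were at 0 in con. The same held for Ccdc73 (at least 847-fold), Eif1a (33.9 ± 0.840 CPM, at least 763-fold), Ccdc25 (at least 731-fold), the serine protease gene Prss8 (at least 711-fold), the poly(A) polymerase gene Papolg (at least 668-fold) and Garem1 (at least 644-fold). The urea transporter gene Slc14a1 fell from 220.1 ± 16.02 to 0.170 ± 0.240 CPM and the heterochromatin gene Bahd1 from 185.5 ± 1.27 to 2.16 ± 0.153 CPM (log2 -6.42 ± 0.65). Ints3 of the Integrator complex fell by log2 6.28 ± 0.60 and Phf23 by log2 6.14 ± 0.61. Zbtb22 (log2 -7.59 ± 1.70), Olfml2a (log2 -6.69 ± 1.89), Rps2 (log2 -6.29 ± 1.38) and Rps3a3 (log2 -6.20 ± 1.51) were lower, and Ankrd66 was at least 157.5-fold lower. The class II deacetylase gene Hdac4 rose from 2.47 ± 2.22 to 29.3 ± 3.42 CPM (log2 3.56 ± 0.99, adjusted p = 0.0297). Reads of Rps2 and Rps3a3, which have near-identical copies in the genome, are uncertain in their origin.

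Ribosomal protein genes gave the smallest list p of this contrast. Of them 1 of 75 rose, 15 fell and 59 did not pass, 1 and 14 adjusted over the list alone (median -1.56 against 0.59 over all genes, adjusted p = 1.8e-08, and adjusted p = 0.892 with an estimated correlation, a value shared by the 4 lists called here). The median log2(CPM + 1) over members was 3.20 in con replicate 1, 5.49 in con replicate 2, and 3.31 and 3.15 in SAHA, so on this measure the shift rested mainly on con replicate 2. Rps12 (log2 -5.05 ± 0.55), Rpl26 (14.8 ± 11.7 to 0.398 ± 0.242 CPM) and Rpsa (log2 -2.96 ± 0.54) fell. Mitochondrially encoded genes had 4 of 13 lower, 4 adjusted over the list alone (median -1.35, adjusted p = 0.044), with mt-Co1 falling by log2 2.40 ± 0.63. The methylation list had 5 of 26 higher and 8 lower, 6 and 9 adjusted over the list alone (median -0.47, adjusted p = 0.044), with Kmt2b (log2 -4.68 ± 0.39) lower and Kmt2d (log2 2.60 ± 0.34) higher. Corepressor subunits had 4 of 23 higher and 6 lower, 5 and 7 adjusted over the list alone (adjusted p = 0.044 toward lower), and their median of -0.94 differed in sign from their mean of 0.11. Chd4 (log2 -2.02 ± 0.51) fell and Ncor1 (log2 2.06 ± 0.57) rose. With DESeq2's size factors 1 list passed. In all, 3382 genes were higher and 1129 lower, 2190 of the higher ones at 0 in con. The count was 219 without SAHA replicate 1, where 2 lists passed, and 361 without SAHA replicate 2, where 1 passed, while 1 and 2 lists passed without con replicate 1 and without con replicate 2. Hltf, Ccdc25, Prss8, Ankrd66, Zbtb22, Olfml2a, Rps2, Rps3a3 and Hdac4 lost their calls without either SAHA library.

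Overexpression of Hdac3 on top of exposure was compared with each PSMPs group, as the labels do not give its route of exposure. Against in vitro PSMPs, Hdac3 rose 22.8-fold (282 ± 76.1 against 12.3 ± 4.21 CPM, log2 4.51 ± 0.50, adjusted p = 0.0084). Trim21 (ENSMUSG00000030966.13, chromosome 7, 102557921 to 102565486), which encodes a ubiquitin ligase that binds antibodies inside cells, rose from 6.96 ± 1.05 to 2033 ± 517 CPM (log2 8.19 ± 1.10, adjusted p = 0.012). Trim21 was at or below 1.02 CPM in all con, in vivo PSMPs, con-in vitro and SAHA libraries. Ribosomal protein genes followed, with rises of Rpl26 (2.19 ± 0.463 to 167 ± 27.7 CPM, log2 6.25 ± 0.85), Rpl36a (47.0-fold higher), Rpl27a (log2 5.18 ± 0.78) and Rpl28 (log2 5.00 ± 1.15). Usp27x, a deubiquitinase gene (log2 5.88 ± 1.10), Zbtb7b (log2 5.16 ± 1.19) and Csrnp1 (log2 5.06 ± 0.80) rose too. Idi1, an isomerase of sterol synthesis, fell from 96.6 ± 55.3 to 1.80 ± 0.154 CPM (log2 -5.74 ± 0.90) and Bmp5, a growth factor gene, from 233 ± 71.9 to 5.91 ± 0.903 CPM (log2 -5.30 ± 0.80). Also lower were Btn1a1 (log2 -5.78 ± 1.20), Septin12 (log2 -5.66 ± 1.05), the relaxin family gene Rln3 (log2 -4.80 ± 0.97) and the lipase gene Pnpla3 (log2 -4.78 ± 0.79). Falls were seen too in Rex2 (log2 -4.50 ± 0.93), H2-Aa (log2 -4.46 ± 0.92), Zfp735 (log2 -4.17 ± 0.82) and Prrg1 (log2 -4.14 ± 0.89).

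As a list, ribosomal protein genes were shifted upward, 26 of 75 higher, 0 lower and 49 not called, and 57 higher adjusted over the list alone (median 3.03 against 0.09 over all genes, adjusted p = 2.9e-22, and adjusted p = 0.966 with an estimated correlation, a value shared by the 3 lists called here). Examples were Rps12 (8.94 ± 1.41 to 199 ± 45.2 CPM), Rpsa (log2 4.12 ± 0.57) and Rps16 (log2 3.72 ± 0.51). These genes took 1.80% (95% Wilson interval 1.79% to 1.81%) and 1.87% (1.86% to 1.88%) of counts in the PSMPs & OE-Hdac3 libraries. Their share was 0.267% (0.264% to 0.271%) and 0.167% (0.165% to 0.169%) in in vitro PSMPs and 0.233% (0.232% to 0.235%) and 0.598% (0.595% to 0.600%) in con. Meiotic cell cycle genes were shifted downward, 9 of 39 lower, 0 higher and 30 not called, 14 lower and 2 higher adjusted over the list alone (median -0.79, adjusted p = 0.00043). Those lower included Ccnb1 (4306 ± 1178 to 834 ± 154 CPM), Ccnb2 (log2 -2.11 ± 0.32), Pttg1 (log2 -2.52 ± 0.45) and Prkar1a (4.01-fold lower). Of 35 oocyte identity genes 7 were lower, 0 higher and 28 not called, 13 lower and 1 higher adjusted over the list alone (median -0.57, adjusted p = 0.0076, a median of -0.02 when scaled by library totals). Among the lower were the oocyte growth factor gene Bmp15 (log2 -2.36 ± 0.31), the maternal effect gene Nlrp5 (log2 -2.50 ± 0.42) and Ddx4 (log2 -2.28 ± 0.40). Of the clearance list, Lsm14b rose (log2 3.91 ± 0.50) while Cnot7 (log2 -3.14 ± 0.35) and Btg4 (log2 -2.08 ± 0.38) fell. Kmt2b (log2 2.68 ± 0.36), Dnmt3a (log2 2.11 ± 0.36) and the corepressor subunit gene Gatad2b (log2 1.88 ± 0.43) rose, while Zfp57 (log2 -3.08 ± 0.56) and Msl3 (log2 -2.35 ± 0.36) fell. For Dnmt3a, Gatad2b, Zfp57, Msl3 and Lsm14b this was opposite to exposure in culture against con-in vitro, a contrast that shares the in vitro PSMPs libraries and so is not independent.

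The test called 309 genes higher and 499 lower, and the count depended on every library of the contrast. It was 0 without PSMPs & OE-Hdac3 replicate 1 (1738 at an unadjusted p under 0.05), 0 without replicate 2 (1893), 241 without in vitro PSMPs replicate 1 and 1 without in vitro PSMPs replicate 2, while DESeq2 called 2576 with all libraries. With library totals the split turned to 548 higher and 306 lower. Hdac3 and the genes named above lost their calls in the 3 fits that gave 0 or 1, where Hdac3 still had log2 from 4.10 to 4.63.

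**Figure D3:**
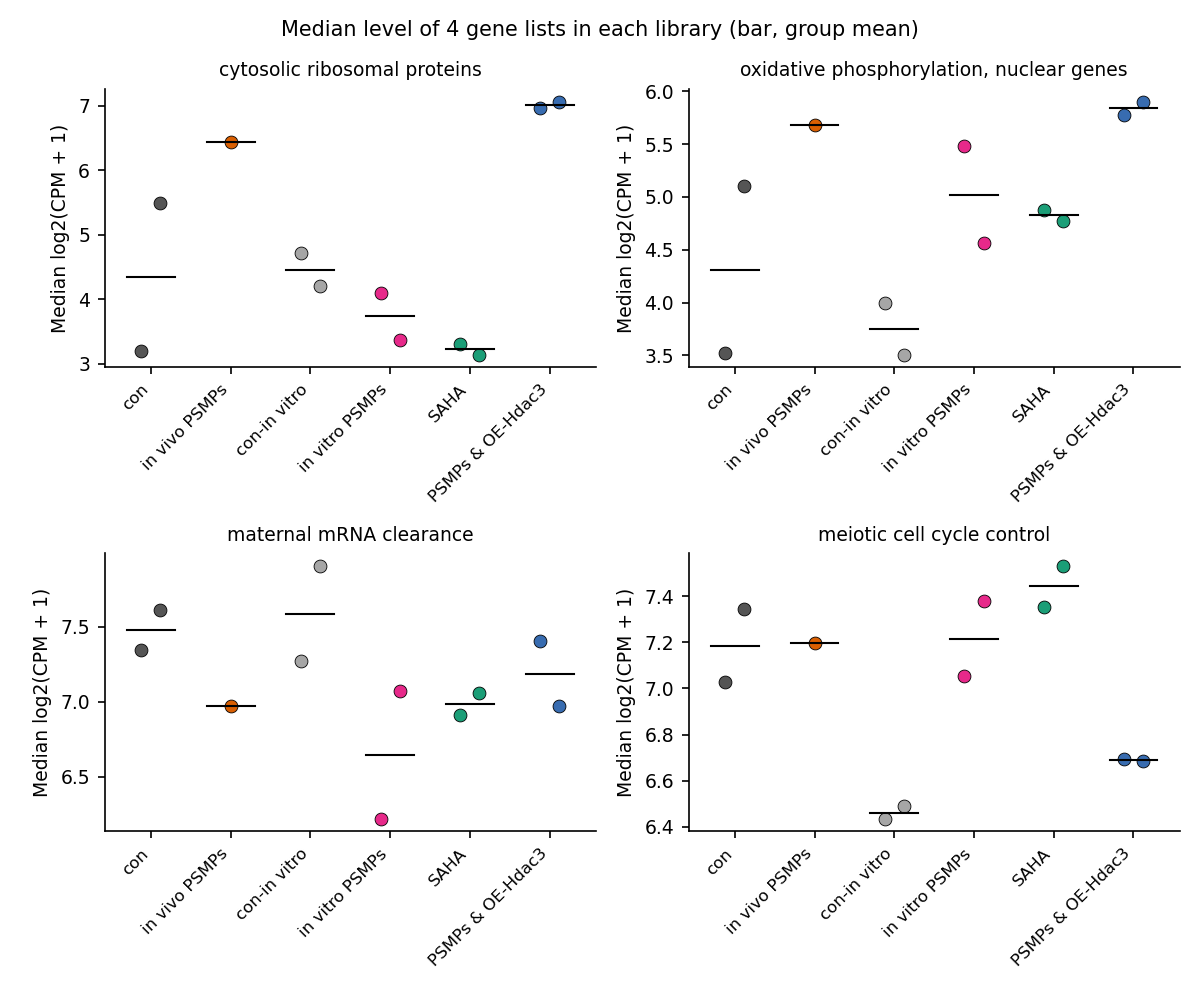
Median log2(CPM + 1) over the members of 4 gene lists in each library, with a bar at each group mean (in vivo PSMPs, n = 1) and vertical axes that do not start at 0. The ribosomal protein list lies highest in the PSMPs & OE-Hdac3 and in vivo PSMPs libraries, and the meiotic cell cycle list lowest in con-in vitro and PSMPs & OE-Hdac3.

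Against in vivo PSMPs, no gene passed by edgeR's quasi-likelihood test (smallest adjusted p = 0.105, 2407 genes at an unadjusted p under 0.05), and DESeq2 called 849. The same edgeR test called 118 genes without a filter on low counts, 331 among genes with 10 counts in every library and 7215 with only these groups fitted, where the spread comes from the 2 overexpressing libraries. Hdac3 passed in each (adjusted p = 0.016, 0.020 and 1.9e-07) and by DESeq2's test (adjusted p = 7.7e-14). It passed as well with the in vivo PSMPs columns as 2 libraries (adjusted p = 0.0067), a setting that lowers the estimated spread. The genes of smallest p are given as values alone. Hdac3 stood at 282 ± 76.1 against 12.7 CPM (log2 4.48 ± 0.68), and Trim21 was at 0 in in vivo PSMPs, at least 27070.2-fold lower than with overexpression. Rbm47 stood at 44.6 ± 16.3 against 2.78 CPM, the ephrin gene Efna5 at 34.5 ± 5.63 against 2.60 CPM, and Prrc2c at 157 ± 18.1 against 15.3 CPM. Sap30, a subunit of the SIN3 deacetylase complex, stood at 178 ± 5.17 against 1017 CPM and the MAPK kinase gene Map2k1 at 189 ± 8.34 against 1206 CPM. Values on the same side were the Polycomb gene Pcgf6 at 96.9 ± 1.14 against 452 CPM, Immp1l at 30.5 ± 1.43 against 313 CPM and Nfxl1 at 120.0 ± 10.5 against 834 CPM.

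Of the lists tested in this contrast 4 passed toward lower values with overexpression, without a called member. Cumulus and granulosa markers had a median log2 of -2.34 against 0.23 over all genes (adjusted p = 0.00015, and adjusted p = 0.125 with an estimated correlation), with Inha at 0.306 ± 0.304 against 59.4 CPM, and 1 of 20 was lower adjusted over the list alone. Meiotic cell cycle genes had a median of -0.53 (adjusted p = 0.0013), with Pde3a at 101 ± 2.65 against 410 CPM and 7 of 39 lower adjusted over the list alone. Mitochondrially encoded genes had a median of -1.77 (adjusted p = 0.0047), with mt-Cytb at log2 -2.53 ± 0.82, and oocyte identity genes a median of -0.30 (adjusted p = 0.026, and 0.00 when scaled by library totals), with 0 of either list called adjusted over the list alone. With an estimated correlation these 3 lists had adjusted p = 0.734.

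The controls themselves differed. Grhl2, an epithelial transcription factor gene, stood at 2651 ± 921 CPM in con-in vitro and at 2 counts in con, a ratio of 88681 (95% counting interval 24549 to 732266). At 0 in con were the decoy receptor gene Il1r2 (281 ± 131 CPM, at least 6423-fold higher), Ly96 (at least 5731-fold), Ap2a2 (at least 5808-fold), Adamts18 (236 ± 23.4 CPM, at least 5295-fold) and the nuclear receptor gene Nr2f2 (at least 4169.8-fold). Also at 0 were Papolg (at least 3846-fold), Gpc3 (at least 3032-fold), the growth factor gene Pdgfa (129 ± 8.34 CPM, at least 2904-fold) and Impact (at least 2744-fold). At 0 in con-in vitro were the ubiquitin ligase gene Ube3b (65.2 ± 5.29 CPM in con, at least 154-fold lower), the tropomyosin gene Tpm4 (at least 101-fold), Guk1 (at least 98.0-fold), Fmr1nb (at least 88.8-fold) and Crym (at least 82.6-fold), besides Cenpu (at least 75.2-fold), Aox4 (at least 73.5-fold), Col9a3 (at least 69.8-fold), Serpinb3a (at least 67.7-fold) and the bile salt exporter gene Abcb11 (at least 61.7-fold). Arf6 (log2 7.49 ± 0.51), Dyrk1a (log2 8.10 ± 0.60) and Cdkn1b (log2 8.83 ± 0.81), which were lower in in vitro PSMPs than in con-in vitro, were higher in con-in vitro than in con, and these contrasts share the con-in vitro libraries. Hdac4 was higher (33.4 ± 21.2 against 2.47 ± 2.22 CPM, log2 3.75 ± 1.00), a call lost without con-in vitro replicate 2.

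No list passed between the controls by the list test, the smallest adjusted p being 0.077. Single members did. In the clearance list 5 of 20 rose and 3 fell, 7 and 3 adjusted over the list alone, with Pan3 (log2 5.64 ± 0.50), Ythdf2 (log2 4.57 ± 0.44), Lsm14b (log2 4.20 ± 0.51) and Btg4 (log2 2.98 ± 0.40) higher in con-in vitro. In the oocyte identity list 2 of 35 rose and 10 fell, 3 and 10 adjusted over the list alone, with H1f8 (log2 -3.98 ± 0.28), Mos (3458 ± 106 to 249 ± 54.1 CPM) and the oocyte growth factor gene Gdf9 (log2 -3.02 ± 0.35) lower. Meiotic cell cycle genes rose in 7 and fell in 12 of 39, 7 and 14 adjusted over the list alone, with Aurkc (log2 -4.75 ± 0.37) and Pttg1 (log2 -4.69 ± 0.50) lower. Oxidative phosphorylation genes rose in 2 and fell in 13 of 76, 2 and 13 adjusted over the list alone (adjusted p = 0.077), with Cox8a (log2 -5.73 ± 0.43) lower.

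The test called 2452 genes higher and 1753 lower in con-in vitro than in con, 1134 of the higher at 0 in con and 354 of the lower at 0 in con-in vitro. With library totals the split turned to 1872 higher and 3025 lower. The count was 6538 without con replicate 2. Lists passed without con replicate 1 (2), con replicate 2 (1) and con-in vitro replicate 1 (1). With only these groups fitted 836 genes were called.

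**Figure D4:**
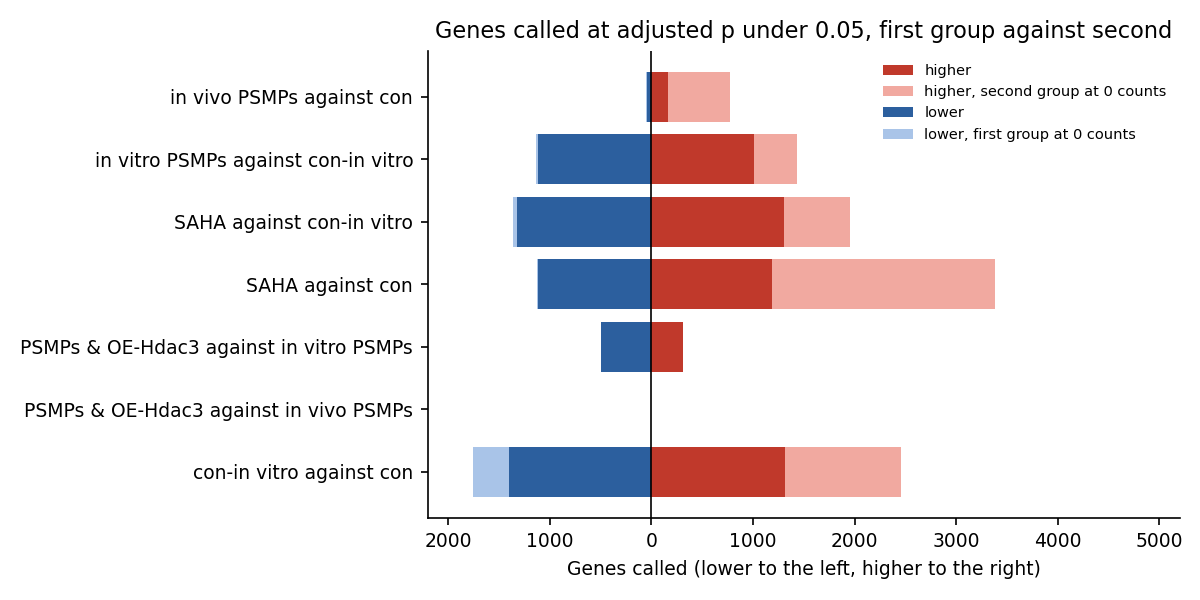
Genes called at an adjusted p under 0.05 in each comparison of groups, lower to the left and higher to the right, with the part at 0 counts in the group of lower level in a pale shade. Exposure in the animal gave 769 higher and 48 lower genes, and overexpression against in vivo PSMPs gave 0 by this test.

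Gene sets called in 1 comparison were then tested in another that shares no library with it. The 1135 genes lower after exposure in culture had a median log2 of -0.75 in SAHA against con, where all genes had 0.59 (adjusted p = 1.9e-15, and adjusted p = 0.239 with an estimated correlation). Of them 407 were also lower there, where 76.6 were expected by chance, and 397 of the 1435 higher genes were also higher, where 290.0 were expected. The 1435 higher genes had a median of 0.71 there (adjusted p = 0.034, and adjusted p = 0.446 with an estimated correlation), and across the 16736 genes, which are not independent replicates, the log2 fold changes had Pearson r = 0.286 and Spearman rho = 0.297. With overexpression against in vivo PSMPs the same higher genes had a median of -0.42 against 0.23 over all genes (adjusted p = 5.2e-08, and adjusted p = 0.239 with an estimated correlation) and the lower genes 0.44 (adjusted p = 0.0097, and adjusted p = 0.446 with an estimated correlation). The 48 genes lower after exposure in the animal had a median of -1.25 in overexpression against in vitro PSMPs, where all genes had 0.09 (adjusted p = 9.7e-09, and adjusted p = 0.285 with an estimated correlation). The same 48 genes did not pass in exposure in culture (median 0.85, 15 called higher and 8 lower, adjusted p = 0.468) or in SAHA against con-in vitro (median 1.10, 20 higher and 8 lower, adjusted p = 0.097). The 769 genes higher after exposure in the animal had a median of 2.33 in exposure in culture (adjusted p = 0.257) and 2.02 in SAHA against con-in vitro (adjusted p = 0.375), medians that turned to -0.30 and -0.63 for the 100 genes of smallest p.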

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

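The tests on sequencing depth and on other cells in the in vitro PSMPs, SAHA and PSMPs & OE-Hdac3 libraries were chosen after the result was seen, and the rest before.

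The effect of exposure in the animal and the effect of exposure in culture differed by a test of the difference itself, for 1886 genes at an adjusted p under 0.05 (edgeR's quasi-likelihood test). The effect was higher in the animal for 1071 and lower for 815, a split that turned to 826 and 1320 with library totals. By the naming rule these included Dhrs7 (fitted log2 19.95), the gap junction gene Gja1 (19.105), Ap2a2 (16.26), Foxd2os (15.94) and Nr2f2 (15.11) on the higher side, and the transketolase-like gene Tktl1 (-21.29), Plac1 (-20.20), the angiopoietin gene Angpt1 (-18.24) and Acbd7 (-15.87) on the lower side. These fitted values rest on groups at 0 or near 0 and are not bounds. Nr2f2 stood at 237 and 137 CPM in con-in vitro, 0.648 and 0.889 CPM in in vitro PSMPs, 0 in con and 1.01 CPM in in vivo PSMPs. Angpt1 stood at 25.2 and 8.35 CPM in con, 0.0258 CPM in in vivo PSMPs, 0 in con-in vitro and 3.00 and 5.25 CPM in in vitro PSMPs. Ribosomal protein genes as a list had a median difference of log2 2.03 (list test adjusted p = 8.3e-05, and adjusted p = 0.933 with an estimated correlation), with Rps26 at log2 5.44 and Rpsa at 3.34. The count was 3740 without con replicate 1, 5028 without con replicate 2, 2972 without con-in vitro replicate 1, 784 without in vitro PSMPs replicate 1 and 618 without in vitro PSMPs replicate 2, and it was 245 with only the 4 groups fitted and 4110 by DESeq2. Each effect is taken against its own control, and the controls differed from each other in 4205 genes, so the difference cannot be placed in the exposed oocytes.

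The control libraries held fewer genes than the others, and after thinning to 6.22 M counts the lowest other library still lay 4256 genes above the highest control (16088 against 11832), which argues against depth. Among 4737 genes at 10 CPM in every exposed or treated library there were 79 cases of a gene at 0 in a con library. In 40.5% of these cases the other con library stood at 10 CPM or more, and in 50% of 130 such cases in con-in vitro. Genes at 0 in both libraries (3 in con, 7 in con-in vitro) were counted in each. Random loss of transcripts at capture or amplification is therefore a candidate explanation, though these cases cover few of the genes missing from the controls. Preparation of con and con-in vitro apart from the other groups, on which the labels are silent, was not tested and would be confounded with every contrast against them. Of 46 markers of other cells, 27 were at 0 in all controls, and 5 (Cyp19a1, Nr5a2, Serpine2, Bmpr1b and Pecam1) were at 10 CPM in every exposed or treated library, but 0 of these 5 were under 1 CPM in every control, so other cell types cannot be told apart from expression by oocytes. In the in vitro PSMPs, SAHA and PSMPs & OE-Hdac3 libraries 25 of 33 markers at 0 in con had at least 1 count and reached at most 3.36 CPM (Cd68), and all 8 tested markers of other ovarian and blood cells had fitted values above con-in vitro in in vitro PSMPs (median log2 4.21, 2 called, list test adjusted p = 0.147) but 4 of 8 above con in SAHA (median -0.35), so a small share of other cells there cannot be excluded. In the in vivo PSMPs library 3 of 11 further granulosa genes were at 0 in con and at 1 CPM or more (Ihh 6.03, Col4a2 5.00 and Lama1 8.51 CPM), between the 4 set for granulosa cell RNA and the 1 set against it, so this count cannot decide between granulosa cell RNA and random loss in con. Loss in con alone would not place this library above the other exposed or treated ones. Inha, at 59.4 CPM here, stood at 0.0909 to 1.53 CPM in the in vitro PSMPs, SAHA and PSMPs & OE-Hdac3 libraries. With overexpression 3 of 20 granulosa markers had fitted values above in vivo PSMPs (median log2 -2.34), while Col4a2 was as high there (5.34 and 6.73 CPM). As in vivo PSMPs is 1 library, granulosa cell RNA in it stays open.

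Ribosomal protein transcripts were high in PSMPs & OE-Hdac3 and in vivo PSMPs. Random lists were matched on expression and on the exonic length given with the counts, in PSMPs & OE-Hdac3 against in vitro PSMPs. Their medians had a central 95% that ended at log2 0.26, against 3.03 for the ribosomal protein list, which argues against exonic length. This length is given per gene and can differ from that of the transcripts present, so an effect of transcript length itself was not tested. In the same contrast the list stayed log2 2.84 or more above all genes with TMM, DESeq2's size factors and library totals. A scaling factor moves all genes of a library nearly alike, so this difference could change little and does not test scaling. Exonic length was not tested for in vivo PSMPs. The in vivo PSMPs library held these transcripts at 1.14% of counts with Hdac3 at 12.7 CPM, below both con libraries, so a raised level of Hdac3 does not explain them there. An effect of Hdac3 in the PSMPs & OE-Hdac3 libraries was not tested and stays open as a hypothesis, but an unrecorded difference in handling between groups was not tested and could give the same values.

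In vitro PSMPs replicate 2 lay as close to the SAHA libraries (correlations across genes of 0.978 and 0.975) as these to each other (0.980). The SAHA libraries lay closer to each other than to in vitro PSMPs replicate 1 by 0.034, which argues against a swap between the groups. Replicate 2 correlated less with replicate 1 of its own group (0.959) than with either SAHA library, so a single wrong label cannot be excluded. Of 4511 genes called in SAHA against con, 76.0% had the same direction in in vitro PSMPs against con-in vitro, where 60.7% of all genes were positive. The rule set beforehand asked for agreement in each library against both controls, while only group fold changes in these contrasts were compared. Both controls held fewer genes, and 2190 of the 3382 genes higher in SAHA were at 0 in con. Some agreement is therefore expected without an effect of exposure or SAHA. A batch shared by these libraries was not tested and could give it too. Exposure and SAHA acting alike stays open, since this test cannot tell it from either.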

How the results depend on the processing

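In vivo PSMPs as 2 libraries, library totals, and genes with 10 counts in every library were chosen after the data were seen. In the counts below, the order is in vivo PSMPs, in vitro PSMPs, SAHA against con-in vitro, SAHA against con, PSMPs & OE-Hdac3 against in vitro PSMPs and against in vivo PSMPs, con-in vitro against con, and the difference of the PSMPs effects, and comparisons within 1.5 times of the count in the report are left out. DESeq2's Wald test called 2693, 4602 and 5327 genes in the first 3, 2576 and 849 with overexpression and 4110 for the difference. Without a filter on low counts, 1370 genes were called for in vivo PSMPs and 118 for overexpression against in vivo PSMPs, and a filter at 50 counts gave 3000 in SAHA against con. With only the groups of a comparison fitted, in vivo PSMPs gave 0 (433 at an unadjusted p under 0.05), SAHA against con 1450, overexpression 5491 and 7215, the controls 836 and the difference 245. With the in vivo PSMPs columns as 2 libraries the counts were 4180, 3917, 1489 and 1355 (overexpression) and 4013 (difference), since columns without independent noise lower the estimated spread. With library totals in vitro PSMPs gave 4231. With 10 counts in every library, where fewer genes are tested, in vivo PSMPs gave 22, SAHA against con 2058, overexpression 1729 and 331 and the controls 2472. With the replicate block, whose libraries share only a number, in vivo PSMPs gave 4, overexpression against in vitro PSMPs 537 and the difference 1210, in vitro PSMPs had 3 lists, and 0 of 10 pairs of groups had a correlation of replicate residuals above 0.1 (highest 0.0599).

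With an estimated correlation 0 lists passed in the 7 comparisons that had any, and with DESeq2's size factors SAHA against con had 1. Of sets carried between comparisons, an estimated correlation ended the calls of the in vitro PSMPs sets in SAHA against con (medians 0.71 and -0.75) and in overexpression against in vivo PSMPs (-0.42 and 0.44), and of the genes lower in in vivo PSMPs in overexpression against in vitro PSMPs (-1.25). Genes higher in in vivo PSMPs reversed in in vitro PSMPs and in SAHA against con-in vitro with the 100 of smallest p (-0.30 and -0.63) and with the replicate block (-0.35 and -0.70), where only 4 genes were called and the 100 of smallest p in that fit formed the set, and passed in overexpression against in vitro PSMPs with both (0.55 and 0.58), while genes higher in in vitro PSMPs no longer passed in SAHA against con with the block (0.59).

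Leaving out 1 library gave 807 to 4336 genes and 0 to 6 lists for in vivo PSMPs, 1096 to 2850 and 3 to 5 for in vitro PSMPs, 1111 to 3347 and 4 to 7 for SAHA against con-in vitro, and 219 to 6657 and 1 to 2 for SAHA against con. It gave 0 to 241 and 3 to 4 for overexpression against in vitro PSMPs, 0 (1133 to 2431 at an unadjusted p under 0.05) and 3 to 4 against in vivo PSMPs, 3644 to 6538 and 0 to 2 for the controls, and 618 to 5028 and 1 to 3 for the difference. Leaving out an in vivo PSMPs column kept the other column, which differed from it by less than counting noise, so no sample was removed. Such fits gave the low end of the gene range for in vivo PSMPs against con and do not test its stability. They are also among the pairs of gene and left-out library counted below. Hdac8 in in vivo PSMPs ran from log2 -1.15 to 2.53 and reversed without con replicate 2. Single genes kept their side of the threshold in 1915 pairs of gene and setting, weakened in 103, strengthened in 65 and reversed in 0, and with 1 library left out in 817, 161, 13 and 1. A change of sign was counted as reversed only where either fit called the gene, and as kept otherwise. The pairs include the histone deacetylase genes and Kat8 in every comparison, and a gene that stayed uncalled counted as kept. Genes not tested in a setting were left out, so genes with 10 counts in every library gave only 75 kept, 4 weakened and 10 strengthened. The counts therefore overstate the stability of called genes. Unless stated, the cause was not tested.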

Other observations

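All tests in this part that compare SAHA with in vitro PSMPs were chosen after the data were seen, and the tests on meiotic stage and interferon before their results were seen.

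After exposure in culture, lists outside the comparisons above held single genes that were called, and none of the lists given here passed its test. Among spindle checkpoint and kinetochore genes 7 of 20 rose and 1 fell in in vitro PSMPs against con-in vitro (median log2 1.27 against 0.71 over all genes, list test adjusted p = 0.243), with Mad2l1 at 1005 ± 288 against 153 ± 76.7 CPM and Cenpa at 121 ± 28.1 against 28.0 ± 12.9 CPM, while Incenp fell (log2 -2.84 ± 0.58). Spindle and microtubule genes had 7 of 27 higher and 2 lower (adjusted p = 0.346), with Prc1 (log2 3.23 ± 0.33) and Ran (log2 3.42 ± 0.36) higher. In the unfolded protein and heat shock list 5 of 29 rose and 4 fell (adjusted p = 0.598), and the 4 lower were large changes: Eif2ak3, the endoplasmic reticulum stress kinase, fell from 1516 ± 560 to 18.2 ± 0.355 CPM, Sdf2l1 from 1362 ± 241 to 30.0 ± 3.82 CPM, Canx from 3954 ± 1159 to 176 ± 25.5 CPM and Pdia4 by log2 3.06 ± 0.42. Con-in vitro stood apart in these genes, since con held Eif2ak3 at 19.6 ± 6.17 CPM, Sdf2l1 at 45.8 ± 25.9 CPM and Canx at 348 ± 155 CPM. Cohesion and meiotic recombination genes had 5 of 22 higher and 1 lower (adjusted p = 0.147), with Hormad1 (log2 4.99 ± 0.78) and Sycp3 (log2 5.25 ± 1.11) higher. In the autophagy list Bnip3, a mitophagy receptor gene, rose (log2 6.75 ± 0.78) (5 of 27 higher, 2 lower, adjusted p = 0.582).

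Between SAHA and in vitro PSMPs, 0 genes were called by edgeR's quasi-likelihood test (407 at an unadjusted p under 0.05) and 5 by DESeq2's Wald test, with a median absolute log2 difference of 0.507. A count of 0 at this group size does not show that the groups were alike.

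The con-in vitro libraries had more of the clearance transcripts Pan3, Lsm14b and Btg4 than con, and a later meiotic stage of the con-in vitro oocytes was tested as a hypothesis. Of 8 transcripts that gain poly(A) tails during maturation, 0 were higher and 4 lower (Mos log2 -3.80, Ccnb1 -2.67, Tpx2 -1.49 and Racgap1 -1.20), and their median lay at log2 -0.99 relative to all genes. Dazl (log2 1.64), Cnot6l (1.48) and Tex19.1 (0.21) had fitted values above 0 without a call. By the rule set beforehand a median at or below that of all genes counted against a later stage, and this median lay below it. The spread over members, an SD of log2 1.90, was not part of that rule. With members on both sides and a spread wider than the shift, this list cannot decide on a later stage.

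Trim21 is induced by interferon in many cells, so an interferon response was tested as a cause of its rise in PSMPs & OE-Hdac3 against in vitro PSMPs. Of 14 interferon-stimulated genes 0 were called higher, with a median log2 of 0.07 relative to all genes, which argues against an interferon response. A transcript of Trim21 introduced together with Hdac3 may be another explanation, and was not tested.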
